A study of Mus musculus with 7 samples.

How the data were processed

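Kidneys of mice at postnatal day 11 were dissociated and sequenced by single-cell RNA sequencing in 7 libraries, 4 from mice homozygous for L2HGDH overexpression and 3 from wild-type mice. Per the labels' protocols, perfused kidneys were minced and digested with warm Liberase TM, hyaluronidase and DNase, then with trypsin, and libraries were made with the 10x Universal 3' V4 chemistry. Groups and replicate numbers were taken from the labels. Per the submitters' processing notes, Cell Ranger 8.0.1, R 4.4.0, Seurat 5.3.0 and the GRCm38 build were used, with no role given for each. The labels state no annotation release, strand setting, cell filter or doublet call.

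The deposited matrix held raw UMI counts of 15843 genes in 91097 cells, and the deposited counts of UMIs and genes per cell equalled sums over the matrix. The deposited percent of mitochondrial UMIs equalled the percent over genes whose symbol starts with mt- and reached 35.0 at most. A deposited score named ISR1, whose gene list no label gives, was used as listed and is treated outside the comparisons. Cluster numbers, class names and library names were used as the authors deposited them, with 28 cluster numbers present. The deposited totals of transformed counts were not used. Within a library, most genes seen in few cells had no entry: the fewest cells with a listed gene were 5 to 14 per library, but 1 listed gene in 100 at most lay below 44 to 48 cells. In all 2399 genes stood at 0 in at least 1 library, from 304 in WT replicate 1 to 1850 in L2HGDH-OE replicate 4, and 13444 were above 0 in all. Such genes are called listed at 0. The counts that could be hidden were bounded only for called or named genes at 0 in every L2HGDH-OE library. Zeros in WT libraries carry no such bound. Doublets were not called here; an alternative filter removed cells above the 99th percentile of UMIs. The lowest UMI count of a cell was 418 and the lowest gene count, in another cell, 205.

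Counts were summed per library, and scaled to CPM for display, over all cells and over each of the 14 classes, each with at least 74 cells in every library (the minimum was set at 20). Library sums ranged from 40.7 to 92.6 M UMIs, and class sums from 0.0839 M (cluster 28, WT replicate 3) to 25.8 M (loop of Henle, WT replicate 1), so folds of weakly expressed genes are loosely fixed in the smallest classes. Sums were compared between genotypes in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood test, genotype as the single term), and p-values were adjusted over all tested genes of a comparison by the Benjamini-Hochberg method at 0.05. L2hgdh, the overexpressed gene, was also adjusted over its 15 comparisons and tested by exact permutation of the library labels, which gives no p below 0.0286. The genotype difference in the proximal tubule was set against that in the other cells of the same library with limma 3.58.1 on differences of log2 CPM (prior count 2). Class shares, quality measures and list levels were compared by exact permutation, and shares also by edgeR on cell numbers. The replicate numbers of the labels were not used to pair libraries in the main tests. Correlations of same-numbered libraries over 9849 genes after removing group means were 0.805, −0.312 and 0.541, and a pair below 0.1 was taken as no pairing. L2HGDH-OE replicate 2 and WT replicate 2 lie in different library sets (closing section), so the negative value does not exclude pairing. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for sums, exact tests and figures. Coordinates came from GENCODE M21 on GRCm38.

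The genes to be named were fixed by a rule before the data were examined: genes passing the test with a mean of at least 10 CPM and no overlap between groups, up to 12 in each direction in all cells and the 3 largest classes and up to 3 in each direction in the others. Where fewer than 5 passed, the 5 lowest p-values in all cells and those 3 classes were named, with up to 4 members of each list; predicted, sex-linked and haemoglobin genes did not fill places. Other names in the report were chosen after their values were seen. The 28 lists were hypoxia (HIF) targets, glycolysis, gluconeogenesis, TCA cycle, 2-hydroxyglutarate metabolism, complex I, complexes III to V, mitochondrially encoded mRNAs, integrated stress response, unfolded protein response, NRF2 targets, fatty acid oxidation, cholesterol synthesis, proximal tubule transporters, tubule injury, nephrogenesis, G2/M, S phase, interferon response, MHC, fibrosis and matrix, imprinted growth genes, 2-oxoglutarate-dependent demethylases and TET, germline genes, mTORC1 and amino acid sensing, immediate early and dissociation genes, haemoglobin and sex-linked genes. Lists with at least 3 tested members were compared by camera in limma with a preset correlation of 0.01, again with an estimated correlation, and by fry, adjusted over lists. Of 14 germline genes 1 was in the matrix and 4 of 5 haemoglobin genes, and neither list reached 3 tested members. List members were also adjusted over the list alone. The integrated stress response and amino acid sensing lists share Slc7a5, Sesn2 and Ddit4, so they are not separate evidence.

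The alternatives fixed beforehand were RLE size factors, no filter on low counts, DESeq2 1.42.0, a replicate block, Xist as covariate, leaving out each library, a stricter cell filter (at least 500 genes, at most 25% mitochondrial UMIs, no cell above the 99th percentile of UMIs), thinning to the smallest library total, equal cell numbers of every class, a minimum of 50 cells, a prior count of 0.5, epithelial classes as the other cells, and shares without immune classes. Alternatives chosen after seeing the data were genes above 0 in every library, robust dispersion, the 5 libraries with Xist at 0, and the library sets described in the closing section, as covariate and each alone. For lists these were also the libraries with Xist at 0 with the set as covariate, and the median percent of mitochondrial UMIs as covariate. All 35 splits of the 7 libraries into 4 and 3 were refitted. Random draws from the data used the seed 20260101 and the simulated counts the seed 11. Before use, the tests were tested on simulated counts with 200 genes changed: in all cells edgeR found 23.9% of 2-fold, 76.1% of 4-fold and 84.8% of 8-fold changes, with 1.6% of calls wrong. In the proximal tubule these were 22.4, 64.2 and 81.8% with 7.44% wrong, so changes of 2-fold could go unseen, and DESeq2 had 34% of calls wrong in all cells and 2.58% in juxtaglomerular cells, against 4.76% there by edgeR. The limma contrast found 0, 31.3 and 81.8%, and camera found a changed list of 20 genes and not an unchanged one, with both correlations. Genes were simulated independently of each other and without library sets. The simulation therefore says nothing on camera where the genes of a list move together.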

Results

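Single-cell RNA sequencing measured gene expression in kidney cell suspensions at postnatal day 11 from mice homozygous for L2HGDH overexpression (L2HGDH-OE, 4 libraries) and from wild-type mice (WT, 3 libraries). L2HGDH is the mitochondrial enzyme that oxidizes L-2-hydroxyglutarate to 2-oxoglutarate. The deposited counts covered 15843 genes in 91097 cells, 45823 from L2HGDH-OE and 45274 from WT libraries, with 402 M unique molecular identifiers (UMIs) in total. The authors' annotation placed these cells in 14 classes. The largest were loop of Henle (19300 cells), proximal tubule (18389), endothelium (12681), smooth muscle (8697), collecting duct principal cells (8534), podocytes (7405) and distal convoluted tubule (6059). The smaller classes were collecting duct intercalated cells (2567), fibrosis-associated fibroblasts (2061), macrophages (1475), B cells (1263), juxtaglomerular cells (802) and 2 classes called here by their cluster numbers. Cluster 28 (1020 cells) carries the authors' annotation monocytes, but its leading genes hold the neutrophil markers S100a8, S100a9 and Retnlg and no macrophage marker. Cluster 30 (844 cells) carries the authors' annotation tubular progenitor and was led by Psca, Igfbp2 and Lypd2, with Akr1b3 further down its leading genes. The authors' name smooth muscle is kept below, but that class was led by Des, Sfrp2 and Cd248. None of the smooth muscle or stromal markers checked was among its leading genes. Of its clusters only cluster 18 (2483 cells) was led by such markers. The median cell held 3260 ± 658 UMIs in L2HGDH-OE and 3759 ± 339 in WT libraries (mean ± SD over libraries, n = 4 and 3 here and below; exact permutation p = 0.286). Mitochondrial transcripts made up 7.69 ± 1.67% and 9.73 ± 3.35% of the median cell (exact p = 0.371), and neither measure passed. Nothing in the labels says that the libraries are separate animals, so the p-values below measure the spread between these samples.

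L2hgdh mRNA was higher in L2HGDH-OE than in WT libraries in all cells together and in each of the 14 classes. In all cells it reached 860 ± 403 CPM against 24.4 ± 4.53 CPM, a log2 fold change of 5.05 ± 0.49 (SE). The L2HGDH-OE libraries held 683, 1346, 999 and 414 CPM and the WT libraries 19.3, 27.9 and 26.0 CPM, so the lowest L2HGDH-OE library stood 14.8-fold above the highest WT library. Among WT classes the proximal tubule held 44.6 ± 5.81 CPM and smooth muscle 2.74 ± 1.81 CPM. The fold was largest in smooth muscle (log2 8.69 ± 0.55, 1321 ± 521 CPM in L2HGDH-OE, 8.40 to 9.49 with a library left out) and endothelium (8.28 ± 0.50). It was smallest in the distal convoluted tubule (4.21 ± 0.38), the proximal tubule (4.32 ± 0.55, 977 ± 631 CPM) and the loop of Henle (4.36 ± 0.43). Adjusted over the 15 comparisons of this gene, edgeR passed it in every comparison (adjusted p = 1.44e-05 in all cells), and the exact permutation p was 0.0286 in each, the lowest that 4 against 3 libraries can give. Adjusted over all tested genes it passed in 12 classes and did not in all cells (edgeR adjusted p = 0.199), loop of Henle (0.0744) or proximal tubule (0.297). WT counts were few in B cells (8 UMIs), cluster 28 (6), juxtaglomerular cells (5) and macrophages (5), so the folds there are loosely fixed. The counts do not separate the endogenous gene, on chromosome 12, from an added copy read as the same gene.

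**Figure D1:**
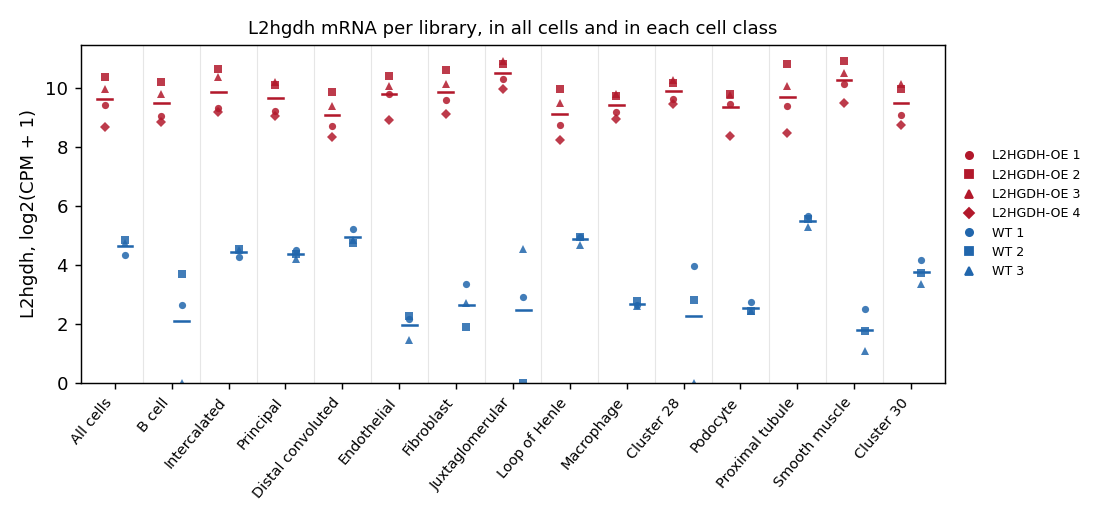
L2hgdh in each library, as log2(CPM + 1) of the summed counts of all cells and of each class. Each dot is 1 library, red for L2HGDH-OE (n = 4) and blue for WT (n = 3), and bars mark group means.

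The genotype difference of L2hgdh was log2 4.10 in the proximal tubule and 5.46 in all other cells of the same libraries. The difference between these values was −1.36 (SE 0.20, limma adjusted p = 0.496 over all genes), and the WT level of L2hgdh was higher in the proximal tubule than in any other class. No gene had a genotype difference that passed as separate between proximal tubule and other cells (limma, 0 of 12832 genes, 603 at unadjusted p < 0.05, no other tool run). Without WT replicate 1 the count was 6.

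In all cells together, genes of the integrated stress response (ISR), in which ATF4 raises amino acid synthesis and transport, were higher as a list in L2HGDH-OE libraries (camera 1.81e-14 with a preset correlation, adjusted p = 0.225 with an estimated correlation). Of 21 tested members 18 were higher, with a median log2 difference of 0.83 (0.77 with Chac1, listed at 0 in every WT library, put at no change). No member passed over all genes and 11 passed adjusted over the list alone. They included Atf5 (93.6 ± 37.3 against 16.8 ± 3.10 CPM, edgeR adjusted p = 0.00165 over the list alone), Asns (22.5 ± 11.9 against 2.87 ± 0.452 CPM, log2 2.90 ± 0.43) and Mthfd2 (log2 1.4 ± 0.26). All 20 immediate early and dissociation genes were higher, among them Socs3 (log2 1.55), Nr4a1 (1.03) and Ier3 (0.87), with a median of 0.80 and 11 passing adjusted over the list alone, 0 over all genes. For this list the camera adjusted p was 3.25e-21, and adjusted p = 0.291 with an estimated correlation. In mean log2(CPM + 1) it read 8.55, 8.58, 8.55 and 7.55 against 7.78, 7.72 and 6.93 (exact p = 0.114), so the genotypes overlapped. All 14 tubule injury genes were higher (median 0.73, 0.62 with Krt20 put at no change; camera 4.17e-10, adjusted p = 0.225 with an estimated correlation). Of these Lcn2 alone passed adjusted over the list alone (96.0 ± 27.5 against 26.1 ± 9.22 CPM), 0 over all genes. Neutrophil genes had higher means in the same sums (S100a9 264 against 30.5 CPM, S100a8 170 against 25, Retnlg 51 against 2.37). L2HGDH-OE replicate 1 was the highest for each (S100a9 653, 170, 105 and 130 CPM). Each was listed at 0 in WT replicate 3, and Retnlg also in WT replicate 2. Lcn2 reached 4261 CPM in cluster 28, so neutrophils may make part of its difference. No single gene passed edgeR in all cells (0 of 14824, 398 at unadjusted p < 0.05), while DESeq2 called 70. The 5 lowest p-values belonged to L2hgdh, Atf5 (log2 2.43 ± 0.33, edgeR adjusted p = 0.581), Cd14 (1.35 ± 0.19, 21.5 ± 4.93 against 8.03 ± 1.16 CPM), Chac1 and Ms4a1. Chac1 was listed at 0 in every WT library (L2HGDH-OE 1.45, 4.96, 4.47 and 2.21 CPM), where hidden counts were not bounded. Ms4a1 was listed at 0 in every L2HGDH-OE library (WT 4.75, 5.3 and 1.88 CPM, and hidden counts could reach 3.40 CPM). By the same edgeR test, L2HGDH-OE replicates 1 and 2 with WT replicate 1 differed from the other 4 libraries in 5014 genes, and both of these sets hold both genotypes.

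Nuclear genes of the respiratory chain were lower as lists in all cells of L2HGDH-OE libraries, though their levels per library overlapped between genotypes. All 37 complex I subunits were lower (median log2 −0.47; camera 2.94e-12, adjusted p = 0.495 with an estimated correlation), led by Ndufa1 (−0.81), Ndufc1 (−0.79) and Ndufa3 (−0.68). In mean log2(CPM + 1) they read 7.25, 7.45, 7.98 and 8.34 against 7.79, 8.24 and 8.58 (exact p = 0.286), a difference of −0.45 that became −0.28 without L2HGDH-OE replicate 1 and −0.26 without WT replicate 3. For complexes III, IV and V a difference of −0.50 became −0.31 without either library. Other measures of the libraries varied alongside. The median mitochondrial share was 6.45, 6.58, 7.67 and 10% against 7.03, 8.69 and 13.5%. By this share the libraries ranked in the same order as by complex I level. The proximal tubule made up 12.2, 17.2, 23.4 and 28.7% of cells against 4.25, 27.8 and 36.8%. Class numbers were not held equal in the list tests of all cells. The nuclear RNA Malat1 was at 51200, 46100, 27190 and 26940 CPM against 48460, 26330 and 26050. All 33 subunits of complexes III, IV and V were lower (median −0.53; camera 7.98e-12, adjusted p = 0.495 with an estimated correlation), among them Atp5k and Cox7c. All 20 tricarboxylic acid (TCA) cycle genes (−0.32; camera 1.43e-06) and all 13 mitochondrially encoded mRNAs (−0.33; camera 3.88e-04) were lower (each adjusted p = 0.495 with an estimated correlation). Glycolysis (−0.25; camera 0.0158, adjusted p = 0.595 with an estimated correlation) and cholesterol synthesis (−0.17; 0.0145, adjusted p = 0.644 with an estimated correlation) were lower by less. All 18 G2/M genes were lower, Ccnb2 by −0.68 and Cenpf by −0.53 (median −0.47; camera 3.12e-06, adjusted p = 0.495 with an estimated correlation), as were all 18 S phase genes (−0.30; 2.51e-04, adjusted p = 0.595 with an estimated correlation). Both rest largely on L2HGDH-OE replicate 2. G2/M genes read 4.83, 2.76, 4.93 and 5.55 against 4.97, 5.46 and 5.22 in mean log2(CPM + 1). Without that replicate their difference of −0.70 became −0.11 and that of S phase genes turned from −0.38 to 0.03. No member of these 8 lists passed, either over all genes or adjusted over the list alone. The 80 ribosomal protein genes, compared as a control, had a median of 0.08.

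Lists of nephrogenesis (median 0.31; camera 1.43e-06, adjusted p = 0.225 with an estimated correlation), mTORC1 and amino acid sensing (0.36; 1.71e-04, adjusted p = 0.491 with an estimated correlation) and interferon response (0.39; 3.22e-04, adjusted p = 0.495 with an estimated correlation) were higher in all cells. So were the 2-oxoglutarate-dependent demethylases with TET enzymes (0.20; 2.17e-04) and MHC class I and II genes (0.24; 0.00650), each at adjusted p = 0.495 with an estimated correlation. Wnt4 was the single nephrogenesis gene to pass adjusted over the list alone (log2 0.83, 7.72 ± 0.591 against 4.20 ± 1.08 CPM), and no gene of these 5 lists passed over all genes. The sex-linked list (5 tested genes) was called lower (median −0.56, camera 6.10e-04, adjusted p = 0.407 with an estimated correlation), although Xist had a higher mean in L2HGDH-OE. Ddx3y and the other Y genes were at 0 in L2HGDH-OE replicates 3 and 4, where Xist held 1212 and 1515 CPM against 0 in the other 5 libraries. Genes of 2-hydroxyglutarate metabolism were not called as a list (camera 0.638), with L2hgdh the 1 member to pass adjusted over the list alone. Nor were hypoxia (HIF) targets (0.819), gluconeogenesis (0.528), the unfolded protein response (0.528), fatty acid oxidation (0.401), fibrosis and matrix (0.335), imprinted growth genes (0.248), proximal tubule transporters (0.146) or NRF2 antioxidant targets (0.0908). In total 17 of 26 lists were called, 8 higher and 9 lower, against 0 with the estimated correlation and 0 by fry.

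In podocytes of L2HGDH-OE libraries the ISR genes Atf5, Asns, Mthfd2, Phgdh, Trib3 and Aldh1l2 were higher, each passing over all genes. Atf5 rose from 22.9 ± 3.95 to 312 ± 97.3 CPM (log2 3.69 ± 0.30, edgeR adjusted p = 7.67e-04), Asns from 2.08 ± 0.367 to 51.4 ± 18.9 CPM (4.57 ± 0.39, 9.12e-04) and Mthfd2 from 3.21 ± 0.243 to 75.8 ± 27.2 CPM (4.44 ± 0.34, 7.29e-04). The serine synthesis gene Phgdh rose from 46.3 ± 15.1 to 214 ± 35.8 CPM (2.13 ± 0.23, 0.00646). Trib3 averaged 38.6 ± 20.8 CPM (edgeR adjusted p = 0.00565) and was listed at 0 in WT replicates 2 and 3. Hidden counts were not bounded there, so the size of its rise is not fixed. The mitochondrial folate gene Aldh1l2 (10.2 ± 3.90 CPM, adjusted p = 0.00754), the arginine carrier Slc7a1 (log2 1.80), Ctsc (1.38) and Ccnd2 (1.64) rose as well. All 18 tested ISR genes were higher (median 2.22, 2.15 with genes listed at 0 in a group put at no change; camera 3.16e-29, adjusted p = 0.174 with an estimated correlation), 6 passing over all genes and 15 adjusted over the list alone. Immediate early genes were higher (median 1.75; 4.45e-17, adjusted p = 0.248 with an estimated correlation), 0 over all genes and 14 adjusted over the list alone. Slc7a5 and Sesn2, both also in the ISR list, led 4 genes of the amino acid sensing list that passed adjusted over the list alone, 0 over all genes. That list was higher (median 0.42, camera 2.06e-04, adjusted p = 0.174 with an estimated correlation). So was the fibrosis and matrix list with Ccn1 and Ccn2 (0.81; 0.00167, adjusted p = 0.174 with an estimated correlation; 2 genes adjusted over the list alone, 0 over all genes). In total edgeR called 14 genes of 10764, all higher. With L2HGDH-OE replicates 1 to 4 left out in turn the count was 27, 16, 7 and 190. It was 4, 5 and 8 with WT replicates 1 to 3 left out, and DESeq2 gave 114. Beside L2hgdh, single calls were followed for Trib3 and Asns only. Trib3 lost its call without WT replicates 1 (edgeR adjusted p = 0.0737) and 2 (0.0682). By these counts other genes named above lost theirs there too, most of them without WT replicate 1.

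Juxtaglomerular cells combined the ISR with immediate early genes, and here members of both lists passed over all genes. Atf5 rose from 32.7 ± 5.64 to 382 ± 161 CPM (log2 3.54 ± 0.39, edgeR adjusted p = 2.81e-04) and Mthfd2 from 9.62 ± 2.13 to 147 ± 48.9 CPM (3.78 ± 0.46, 7.28e-04). Cdkn1a, of the injury list, rose from 13.3 ± 7.78 to 94.7 ± 40.1 CPM (log2 2.94 ± 0.52, edgeR adjusted p = 0.0160). Asns rose from 1 WT UMI to 100 (ratio 59.0, 95% counting interval 10.4 to 2353) and the chemokine Cxcl1 from 1 to 260 (ratio 153, 27.3 to 6080). These intervals pool UMIs over libraries and leave out the spread between libraries. Cxcl1 read 239, 366, 129 and 17.0 CPM in L2HGDH-OE against 0, 0 and 7.38 CPM in WT libraries. Fos rose from 674 ± 82.3 to 2337 ± 487 CPM (log2 1.75 ± 0.23, 0.00139) and Zfp36 from 67.6 ± 43.4 to 418 ± 156 CPM (2.49 ± 0.39, 0.00599). Junb (log2 2.21), Egr1 (2.20), Socs3 (3.27), Atf3 (2.96), Cebpb (2.55) and Nupr1 (2.64) also rose. Krt19, with no WT UMI, averaged 63.7 CPM in L2HGDH-OE libraries (46.3, 106, 97.3 and 5.67 CPM, edgeR adjusted p = 0.0287). This mean is 14.8-fold a floor of 3 UMIs pooled over WT libraries (4.30 CPM), but L2HGDH-OE replicate 4 lies near that floor. Krt19 is a keratin of epithelium, with higher means in principal cells too (65.8 ± 28.9 against 24.5 ± 8.77 CPM). Background RNA from other cells was not estimated. Dclk1 fell from 69.4 ± 21.6 to 14.1 ± 6.67 CPM (−2.37 ± 0.45, 0.0244) and Nrgn from 148 ± 46.7 to 39.5 ± 9.08 CPM (−1.89 ± 0.31, 0.00930). All 12 ISR genes were higher (median 1.86; camera 1.56e-13, adjusted p = 0.0821 with an estimated correlation; 5 over all genes, 11 adjusted over the list alone). All 19 immediate early genes were higher (median 1.51; 2.31e-24, adjusted p = 0.0821 with an estimated correlation; 9 over all genes, 18 adjusted over the list alone). For both lists fry gave an adjusted p of 0.0338. The 25 genes called of 5281 (23 higher, 2 lower) became 14, 20, 8 and 169 with L2HGDH-OE replicates 1 to 4 left out in turn, and 5, 9 and 12 with WT replicates 1 to 3 left out. Beside L2hgdh, single calls were followed for Dclk1, Krt19, Cxcl1 and Nrgn only. With 5 genes called without WT replicate 1, most of the other genes named above lost their calls there. Dclk1 lost its call in every such fit but that without L2HGDH-OE replicate 4 (edgeR adjusted p up to 0.239). Krt19 lost it without each WT library (up to 0.191) and Cxcl1 without WT replicates 1 and 2 (up to 0.135). Nrgn lost it without L2HGDH-OE replicate 3 and WT replicates 2 and 3 (up to 0.0729).

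In the class annotated smooth muscle and in endothelium few single genes passed. In smooth muscle Asns rose from 1.51 ± 0.0900 to 58.7 ± 39.9 CPM (log2 5.28 ± 0.67, edgeR adjusted p = 0.0387) and Zfp36 from 120 ± 7.31 to 570 ± 184 CPM (2.26 ± 0.28, 0.0375), while Slitrk4 was listed at 0 in every L2HGDH-OE library (WT 9.48, 10.2 and 12.6 CPM; hidden counts could reach 38 CPM). All 21 ISR genes were higher there (median 2.03, 1.61 with genes listed at 0 in a group put at no change; camera 1.37e-22, adjusted p = 0.390 with an estimated correlation; 1 over all genes, 18 adjusted over the list alone). All 20 immediate early genes were higher (1.81; 3.63e-24, adjusted p = 0.390 with an estimated correlation; 1 over all genes, 16 adjusted over the list alone). The amino acid sensing list was higher too (median 1.02, camera 1.68e-07, adjusted p = 0.390 with an estimated correlation, 0 over all genes and 6 adjusted over the list alone). It was led by Slc7a5 (40.3 ± 24.6 against 2.62 ± 0.380 CPM), which is also in the ISR list. In endothelium Cxcl1 rose from 12.9 ± 0.981 to 55.2 ± 14.2 CPM (log2 2.13 ± 0.22, edgeR adjusted p = 0.0226), and Plet1os was listed at 0 in every L2HGDH-OE library (WT 9.41, 14 and 15.4 CPM; hidden counts could reach 10.8 CPM). All 21 endothelial ISR genes were higher (1.11, 1.07 with genes listed at 0 in a group put at no change; camera 3.17e-27, adjusted p = 0.382 with an estimated correlation; 0 over all genes, 16 adjusted over the list alone). Endothelial immediate early genes were higher by 1.12 (6.28e-23, adjusted p = 0.382 with an estimated correlation; 0 over all genes, 14 adjusted over the list alone). Smooth muscle had 4 called genes of 11244 (14, 11, 1 and 182 with L2HGDH-OE replicates 1 to 4 left out in turn, 1 without each WT library) and endothelium 3 of 12039 (7, 8, 1 and 46, then 4, 1 and 1 without WT replicates 1 to 3). Without L2HGDH-OE replicate 3, or any WT library, Asns and Zfp36 in smooth muscle (edgeR adjusted p up to 0.294) and Cxcl1 and Plet1os in endothelium (up to 0.304) lost their calls. With the library sets of the closing section as covariate only L2hgdh stayed called in smooth muscle, so Asns and Zfp36 lost their calls there too.

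**Figure D2:**
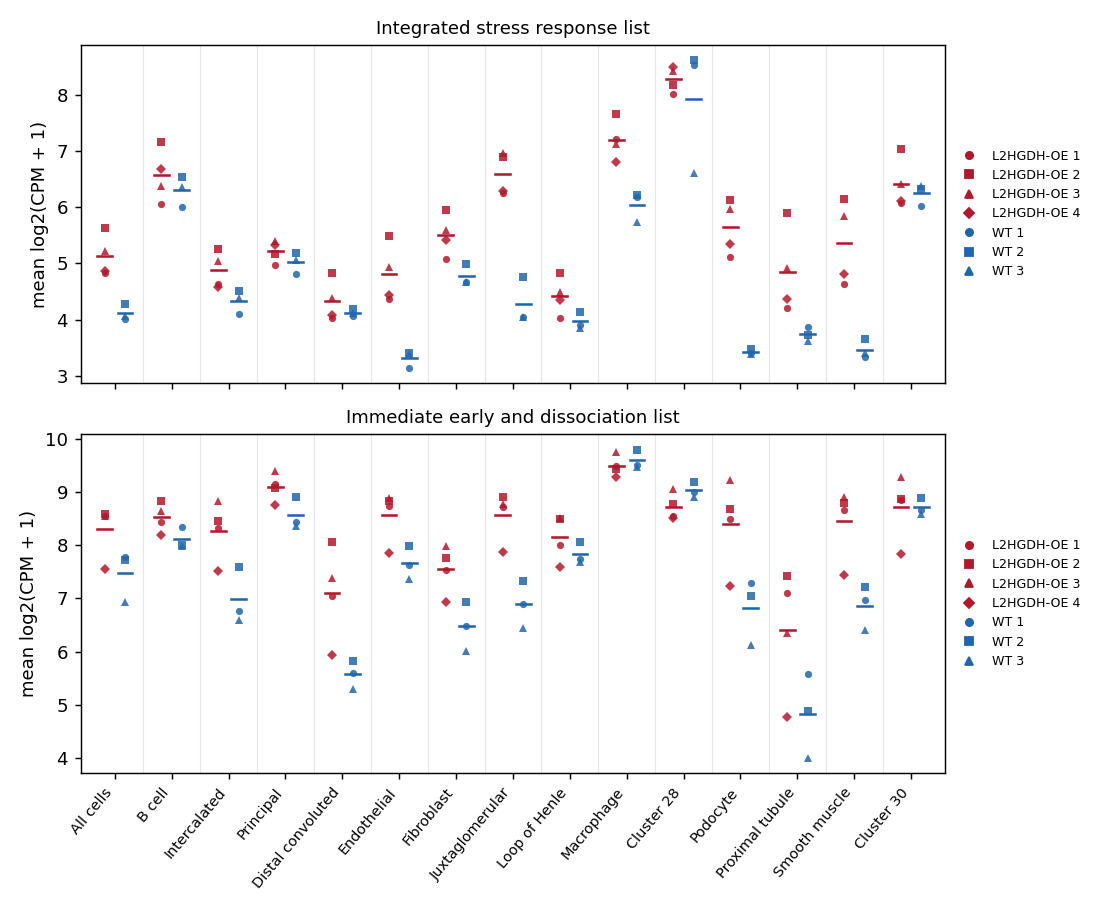
Mean log2(CPM + 1) over the ISR list and over the immediate early and dissociation list in each library, for all cells and each class. Each dot is 1 library, red for L2HGDH-OE (n = 4) and blue for WT (n = 3), and bars mark group means.

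In the proximal tubule of L2HGDH-OE libraries, stress and injury lists were higher and the transporters of the mature tubule were lower. ISR genes had a median of 1.64 (1.17 with genes listed at 0 in a group put at no change; camera 2.39e-07, adjusted p = 0.457 with an estimated correlation), 0 passing over all genes and 8 adjusted over the list alone. Immediate early genes had a median of 1.95 (4.94e-14, adjusted p = 0.457 with an estimated correlation, 0 over all genes, 15 adjusted over the list alone). Their levels overlapped, at 7.10, 7.43, 6.35 and 4.77 against 5.58, 4.895 and 4.01 in mean log2(CPM + 1) (exact p = 0.143). Injury genes had a median of 0.82 (0.71 with genes listed at 0 in a group put at no change; 2.06e-05) and transporters of −0.35 (0.00115), each at adjusted p = 0.457 with an estimated correlation and with no member passing. In mean log2(CPM + 1) injury genes read 5.04, 5.95, 4.84 and 4.25 against 4.58, 4.29 and 3.82, and their difference of 0.79 became 0.48 without L2HGDH-OE replicate 2. Cdkn1a, of the injury list, measured 187 ± 92.4 against 76.3 ± 11 CPM (log2 1.16 ± 0.33, edgeR adjusted p = 0.0865 over the list alone). No gene passed edgeR (0 of 12941, 547 at unadjusted p < 0.05, 27 by DESeq2). Beside L2hgdh the lowest p-values were of Apob, Agmo, Tmem88b and Chrna7, each listed at 0 in every L2HGDH-OE library (Apob in WT 4.72, 6.22 and 7.33 CPM; hidden counts could reach 8.17 CPM, and no loss is established for these genes).

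In the loop of Henle and the collecting duct injury genes were higher as a list, and ISR genes less steadily so. In the loop of Henle the injury list was higher (median 1.18; camera 2.98e-11, adjusted p = 0.385 with an estimated correlation), and 6 genes passed adjusted over the list alone, among them Lcn2 (39.7 ± 24.1 against 5.90 ± 1.56 CPM, log2 2.71 ± 0.54), Clu (1.18) and Anxa3 (1.91). No gene passed over all genes there (edgeR 0 of 12910, 287 at unadjusted p < 0.05, 12 by DESeq2), and the ISR list had a median of 0.24 (0.00243, adjusted p = 0.503 with an estimated correlation; 0 over all genes and 0 adjusted over the list alone). In principal cells the injury list was higher (0.79; 4.45e-10, adjusted p = 0.140 with an estimated correlation), with Lcn2 (408 ± 130 against 154 ± 54.4 CPM) and Clu passing adjusted over the list alone, 0 over all genes. Their ISR list had a median of 0.23 (0.00383, adjusted p = 0.350 with an estimated correlation; 0 over all genes, 2 adjusted over the list alone). The ISR calls of loop of Henle and principal cells were lost with Xist as covariate (camera 0.334 and 0.403), among the libraries with Xist at 0 with and without the library set as covariate, with the replicate block, without L2HGDH-OE replicate 4 and without WT replicate 1 (0.121 in both). In principal cells the ISR difference in mean log2(CPM + 1) fell from 0.20 to 0.10 without WT replicate 1. Principal cells also had a higher interferon list (0.64; 2.91e-06, adjusted p = 0.0847 with an estimated correlation; fry 0.0142), of which Oasl2 passed adjusted over the list alone, 0 over all genes. In intercalated cells Dusp5 rose from 2.84 ± 1.71 to 26.5 ± 8.29 CPM (log2 3.00 ± 0.41, edgeR adjusted p = 0.0212) and Cebpb from 35.6 ± 4.16 to 156 ± 73.9 CPM (2.13 ± 0.32, 0.0338). Intercalated ISR genes were higher (0.59; 4.47e-06, adjusted p = 0.234 with an estimated correlation; 1 over all genes, 6 adjusted over the list alone), as were injury genes (0.52; 4.55e-05, adjusted p = 0.163 with an estimated correlation; 0 over all genes, Lcn2 adjusted over the list alone). Immediate early genes were higher by 1.20 in intercalated cells (1.44e-30, adjusted p = 0.234 with an estimated correlation; 0 over all genes, 19 adjusted over the list alone). They were higher by 1.80 in the distal convoluted tubule (3.89e-21, adjusted p = 0.416 with an estimated correlation; 0 over all genes, 18 adjusted over the list alone, led by Fos at 1189 ± 564 against 205 ± 54.3 CPM). L2hgdh was the 1 gene called in principal cells and in the distal convoluted tubule. The 3 genes of intercalated cells became 114 without L2HGDH-OE replicate 4; without L2HGDH-OE replicate 3 or WT replicates 2 or 3 Dusp5 (edgeR adjusted p up to 0.167) and Cebpb (up to 0.198, and 0.275 without WT replicate 1) lost their calls.

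Among immune cells, Ms4a1, the gene of CD20, had no entry in B cells of any L2HGDH-OE library. Ms4a1 was listed at 0 there against 682, 757 and 424 CPM in WT, and Gimap3 was listed at 0 against 122, 246 and 206 CPM. Most genes seen in few cells of a library were listed at 0, and such hidden counts could reach 761 CPM for Ms4a1 and 375 CPM for Gimap3 in B cells, so a loss is not established. In macrophages Hilpda rose from 23.2 ± 4.23 to 98.9 ± 23.6 CPM (log2 2.13 ± 0.33, edgeR adjusted p = 0.0286). The macrophage ISR list was higher (1.14; camera 1.54e-05, adjusted p = 0.155 with an estimated correlation; 0 over all genes, 4 adjusted over the list alone), whereas immediate early genes stayed level (−0.08, camera 0.386). Cdkn1a, of the injury list, measured 348 ± 62.9 against 122 ± 53.2 CPM in macrophages (1.53 ± 0.29, edgeR adjusted p = 6.79e-04 over that list alone). In cluster 28 the neutrophil genes Lrg1 (860 ± 341 against 52.0 ± 45.6 CPM, log2 3.95 ± 0.56, adjusted p = 0.0197, listed at 0 in WT replicate 3) and Lcn2 (4261 ± 1474 against 529 ± 459 CPM, 3.08 ± 0.58, 0.0492) rose, with Cd14 (1.96), Hp (1.83) and Anxa1 (1.88). Counts of Lrg1 hidden in WT replicate 3 were not bounded, so the size of its rise is not fixed. Glycolysis genes were higher in cluster 28 (0.50; 9.57e-06, adjusted p = 0.218 with an estimated correlation; 0 over all genes, 4 adjusted over the list alone, led by Gapdh and Ldha). There neutrophil genes had higher means (S100a9 41980 against 8371 CPM, Retnlg 8796 against 593) and monocyte genes lower means (Lyz2 8965 against 10400 CPM, Csf1r 273 against 407). S100a9 was listed at 0 in WT replicate 3 and Retnlg in WT replicates 2 and 3, where hidden counts were not bounded. A different mix of cells may make this glycolysis difference. The 14 genes called in cluster 28, all higher, became 1, 8, 2 and 33 with L2HGDH-OE replicates 1 to 4 left out in turn and 35, 1 and 3 with WT replicates 1 to 3 left out. Lrg1 and Lcn2 lost their calls without WT replicate 2 (edgeR adjusted p up to 0.259) and L2HGDH-OE replicates 1 and 3. Without WT replicate 2 or L2HGDH-OE replicate 1 only L2hgdh stayed called, so Cd14, Hp and Anxa1 lost their calls too. Hilpda in macrophages kept its call only without L2HGDH-OE replicates 1 and 4 (otherwise up to 0.194), and the 3 genes of B cells became 27 without WT replicate 3.

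Fibroblasts of L2HGDH-OE libraries had higher ISR genes, among them Cebpb (224 ± 99.9 against 89.2 ± 20.5 CPM) and Gdf15 (median 0.75; camera 1.33e-04, adjusted p = 0.431 with an estimated correlation; 0 over all genes, 6 adjusted over the list alone). Their immediate early genes were higher by 1.15 (1.92e-17, adjusted p = 0.431 with an estimated correlation; 0 over all genes, 14 adjusted over the list alone), led by Nr4a1 (83.0 ± 18.3 against 25.4 ± 8.03 CPM). L2hgdh was the 1 gene called in fibroblasts (26 genes without L2HGDH-OE replicate 4, 6 without replicate 2, 4 without WT replicate 1) and the 1 gene called in cluster 30. Cluster 30 showed no ISR difference (camera 0.891), and its NRF2 list was higher (0.45; 0.0131, adjusted p = 0.320 with an estimated correlation; 0 over all genes, Txnrd1 adjusted over the list alone).

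Over the 14 classes, camera with the preset correlation called the ISR list higher in 11 and the immediate early list in 11, neither lower in any. Adjusted p ranged from 0.0821 to 0.997 with an estimated correlation for the ISR and from 0.0821 to 0.988 for the immediate early genes. For the immediate early list every L2HGDH-OE library read above every WT library in 3 classes only (exact permutation, lowest 0.15 adjusted over classes). In 8 classes every L2HGDH-OE library had a higher mean ISR level than every WT library (exact p = 0.0286 in 5 of them, 0.0571 in fibroblasts and proximal tubule and 0.0857 in intercalated cells, lowest 0.08 adjusted over classes), podocytes reading 5.12, 6.13, 5.97 and 5.35 against 3.41, 3.48 and 3.38 in mean log2(CPM + 1). Complex I and complex III to V lists were lower in all 14 classes, with medians from −0.57 to −0.16 and from −0.64 to −0.17 (lowest adjusted p = 0.296 with an estimated correlation for both). The G2/M list was lower in each of the 11 classes where it could be tested (lowest adjusted p = 0.208 with an estimated correlation); in macrophages Cenpe, Mki67, Cenpf and Kif11 were among 5 genes to pass adjusted over the list alone, 0 over all genes. Without L2HGDH-OE replicate 2 the G2/M call held in 7 of these classes and turned to higher in endothelium (camera 1.11e-05), and without WT replicate 1 the ISR call held in 7 of 11 classes. In no class were all L2HGDH-OE libraries below all WT libraries in complex I or complex III to V levels. Summed over classes edgeR called 72 genes, 12 of them L2hgdh itself, and 79, 81, 30 and 799 with L2HGDH-OE replicates 1 to 4 left out in turn, then 64, 24 and 58 without WT replicates 1 to 3.

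The cellular make-up of the suspensions did not differ by genotype past the test, although mean shares of fibroblasts and juxtaglomerular cells were higher in L2HGDH-OE libraries. Fibroblasts made up 3.21 ± 1.25% of L2HGDH-OE cells against 1.18 ± 0.569% (exact permutation p = 0.0571, adjusted 0.4 over classes). Juxtaglomerular cells made up 1.13 ± 0.261% against 0.642 ± 0.155% (exact p = 0.0286, adjusted 0.4). EdgeR on the class counts gave log2 1.44 ± 0.42 for fibroblasts and 0.81 for juxtaglomerular cells (adjusted p = 0.104 for both). Macrophages (1.89 ± 0.309 against 1.36 ± 0.184%) and principal cells (10.4 ± 2.25 against 8.06 ± 1.02%) had adjusted values no lower, and smooth muscle made up 8.78 ± 2.02 against 9.85 ± 2.75% (exact p = 0.543). The proximal tubule share was 20.4 ± 7.22% against 23 ± 16.8% (exact p = 0.8) and varied widely in WT, with 4.25% in replicate 1 against 27.8 and 36.8%. Cells in the clusters led by proliferation genes made up 3.38 ± 2.23% of L2HGDH-OE and 5.34 ± 1.76% of WT libraries (exact p = 0.229), with 0.585% in L2HGDH-OE replicate 2.

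**Figure D3:**
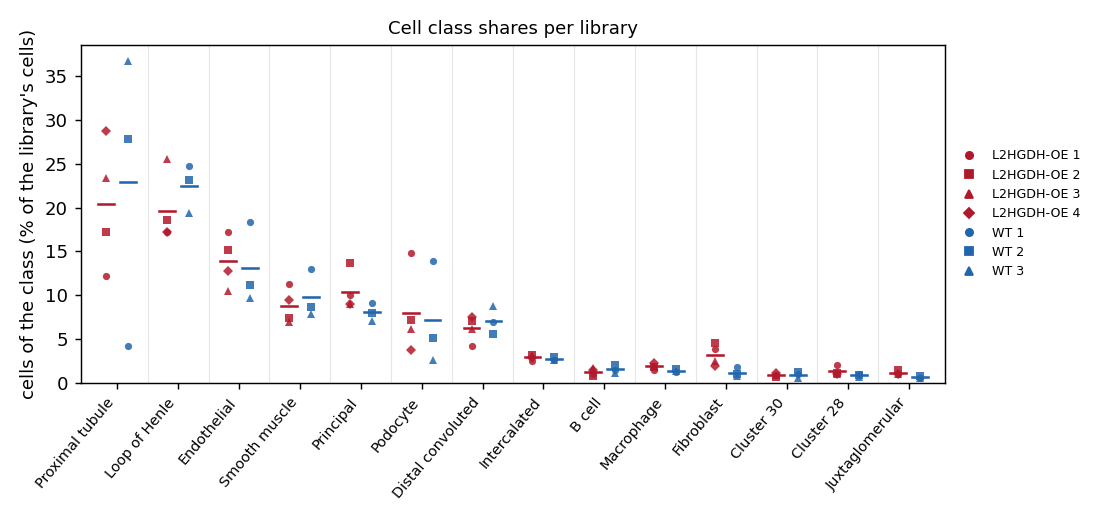
Percent of each library's cells in each class of the authors' annotation. Each dot is 1 library, red for L2HGDH-OE (n = 4) and blue for WT (n = 3), and bars mark group means.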

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

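All tests of explanations and all splits in this part were chosen or read after the results they bear on were seen. Among 195 sets of the 4 L2HGDH-OE values of 1 measure, 12 (6.15%) held a library far from the other 3, where chance gives about 1 in 20; 8 of these were in L2HGDH-OE replicate 2, 3 in replicate 4 and 1 in replicate 1. Replicate 2 had 1.52% juxtaglomerular cells (others 0.964 to 1.02%), an ISR1 score of 0.0621 in the proximal tubule (others −0.00363 to 0.0072) and Fgg at 33.8 CPM in the loop of Henle (others 4.38 to 5.76). In replicate 2 the mean log2(CPM + 1) of G2/M genes was 1.67 in intercalated cells (others 3.34 to 3.59), 3.39 in endothelium (5.77 to 5.84), 1.02 in fibroblasts (4.64 to 4.94) and 3.09 in the loop of Henle (5.46 to 5.69), and that of S phase genes in endothelium was 3.34 (5.10 to 5.22). In replicate 4 the immediate early and dissociation list was at 7.55 in all cells (others 8.55 to 8.58), 7.85 in endothelium (8.73 to 8.89) and 7.44 in smooth muscle (8.66 to 8.91). In replicate 1 cluster 28 held 2.01% of cells (others 1.05 to 1.18%).

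The genotype difference of L2hgdh was smaller in the proximal tubule than in the other cells of the same libraries, by log2 −1.36, with limma's value before adjustment at 2.32e-04 and above the threshold after adjustment over all genes. The deposited ISR1 score, which no comparison of the report used, was higher by 0.0230 in L2HGDH-OE libraries over all cells, every L2HGDH-OE library above every WT library in the means of podocytes (0.0560 against 0.00943) and juxtaglomerular cells (0.0342 against −0.0153). Its exact permutation p over all cells was 0.0571, 0.143 adjusted.

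Higher ISR genes in 11 classes of L2HGDH-OE libraries may reflect the genotype, as a hypothesis, since the lists, the libraries and the tests share the same data. The list was called in 11 classes with the preset correlation, in 0 with the estimated correlation and in 2 by fry. Dissociation stress is not decided in macrophages, where immediate early genes had a median of −0.0823 while the ISR was higher on 6 tested members. Their immediate early level was the highest of all classes in both genotypes (mean log2(CPM + 1) 9.48 in L2HGDH-OE, 9.59 in WT). A lack of difference at that level may not reveal such stress. In 10 other classes both lists were higher, as a response to the warm digestion would need, so that explanation stays open there beside an effect of genotype on both lists. Among the 5 libraries with Xist at 0 both of L2HGDH-OE are in the smaller library set and 2 of 3 WT in the larger. With the set as covariate their genotype term rests on WT replicate 1 alone, so that fit decides nothing. The ISR list passed among these libraries in 8 classes with the preset correlation, and there both L2HGDH-OE libraries read above every WT library. In podocytes they read 5.12 and 6.13 against 3.41, 3.48 and 3.38 in mean log2(CPM + 1). Such levels argue against a sex imbalance as the whole cause in podocytes, juxtaglomerular cells, smooth muscle, endothelium and macrophages. It is not decided in fibroblasts (5.072 and 5.955 against up to 4.995), proximal tubule or intercalated cells. Nor can it be told apart in 3 classes where the list did not pass. There the mean ISR level differed by 0.05 ± 0.15 (SD of L2HGDH-OE) among these libraries against 0.20 ± 0.19 with all in principal cells. In the distal convoluted tubule this was 0.30 ± 0.57 against 0.21 ± 0.37. In the loop of Henle it was 0.46 ± 0.57 against 0.46 ± 0.33. In podocytes, juxtaglomerular cells, smooth muscle, endothelium and macrophages every L2HGDH-OE library of either set read above every WT library. These levels also argue against the library sets as the whole cause there. With the set as covariate in all 7 libraries the list passed in 10 classes with the preset correlation, the distal convoluted tubule being the exception.

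Lower complex I and complex III to V lists in L2HGDH-OE libraries are small shifts called in 14 classes with the preset correlation, in 0 with the estimated correlation and in 0 by fry, and the levels per library passed in no class (lowest adjusted over classes 0.311 and 0.267, exact permutation). A general shift of short and abundant mRNAs is argued against by the ribosomal protein genes of all cells, whose median of 0.0765 (−0.03 to 0.14 between its quartiles) lay apart from −0.47 for complex I (−0.59 to −0.40), and in the 11 classes whose quartiles part in this way, and cannot be told apart in 3 where they overlap: cluster 28, where ribosomal genes were as low (−0.36 against −0.32), B cells (−0.07 against −0.16) and cluster 30 (−0.05 against −0.25). With the preset correlation the complex I list passed in 14 classes with the library set as covariate. It also passed in 14 among the libraries with Xist at 0. Neither call decides on library set or sex. The same call moved this list in 14 classes in 6 of the 35 splits, the real one among them. In no class were the libraries of the genotypes apart, and both L2HGDH-OE libraries with Xist at 0 are of the smaller set. With the mitochondrial share of the libraries as covariate the list passed in 11 classes and not in B cells, macrophages and cluster 30. By the same limit that share is not decided either. A difference in cell stress or energy state at dissociation also stays open, which no value here decides. So does chance, since other splits of the libraries moved as many classes.

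The genes called in cluster 28 may come from a larger share of neutrophils in L2HGDH-OE libraries. More neutrophils in the cluster annotated as monocytes are a candidate explanation, since 5 of 5 neutrophil markers had higher means there. Mean CPM was 41980 against 8371 for S100a9, 26870 against 6637 for S100a8, 8796 against 593 for Retnlg, 490 against 202 for Csf3r and 516 against 63.9 for Cxcr2, and WT replicate 3 was listed at 0 for all 5, WT replicate 2 for Retnlg and Cxcr2, and L2HGDH-OE replicate 4 for Cxcr2. Counts hidden at these zeros were not bounded, so the size of these differences is not fixed. The monocyte genes Lyz2 (8965 against 10400 CPM), Csf1r (273 against 407) and Ccr2 (340 against 514, listed at 0 in L2HGDH-OE replicate 2) had lower means in the cluster. A change within neutrophils of a fixed number stays open. Neutrophils are blood cells. Per the labels' protocols the kidneys were perfused, but no sort that would remove such cells is named.

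The 7 libraries split into 4 and 3 in 35 ways, and a single count exceeds chance where no other split gave as many. Of 34 counts above 0 read afterwards 2 did, where chance alone gives up to about 0.971, so neither excludes chance over the whole set. For called genes this was cluster 28 (14 genes, highest other split 10, 1 split as large), whose count fell to 1, 2, 1 and 3 without L2HGDH-OE replicates 1 and 3 and WT replicates 2 and 3. Where the real count is 0 all 35 splits are as large by construction and the comparison says nothing: all cells (0 genes, highest other 5014, 35 splits), loop of Henle (0, 4070, 35), proximal tubule (0, 1728, 35) and proximal tubule against other cells (0, 15, 35). Chance cannot be excluded for B cells (3, 7, 3 splits), intercalated (3, 456, 4), principal (1, 3488, 5), distal convoluted tubule (1, 1512, 4), endothelium (3, 1231, 6), fibroblasts (1, 36, 7), juxtaglomerular (25, 265, 3), macrophages (2, 194, 6), podocytes (14, 2685, 4), smooth muscle (4, 222, 3), cluster 30 (1, 48, 6) and the 14 classes together (72, 13804, 4). For called lists it was fibroblasts (15 lists, highest other 13, 1 split), with 8 to 14 lists when a library was left out and 0 with the estimated correlation (lowest adjusted p = 0.431). It cannot be excluded for all cells (17, 21, 8 splits), B cells (7, 11, 8), intercalated (10, 18, 13), principal (14, 16, 10), distal convoluted tubule (15, 15, 5), endothelium (12, 17, 17), juxtaglomerular (9, 10, 7), loop of Henle (15, 16, 2), macrophages (9, 11, 10), cluster 28 (6, 9, 7), podocytes (11, 14, 6), proximal tubule (18, 18, 2), smooth muscle (11, 15, 21) and cluster 30 (6, 12, 16). Nor can it for the classes in which a list moved 1 way: ISR (11, 11, 3 splits), immediate early (11, 13, 11), complex I (14, 14, 6), complexes III to V (14, 14, 8), G2/M (11, 11, 2) and tubule injury (9, 9, 2). The splits with far more genes than the real one point to a structure of the libraries. The highest, L2HGDH-OE replicates 1 and 2 with WT replicate 1 against the rest, follows the numbers in the library names, 1 to 3 against 4 to 7, which no label calls a batch.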

How the results depend on the processing

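Genes above 0 in every library, robust dispersion, the libraries with Xist at 0, the library sets and the mitochondrial share as covariate were chosen after seeing the data. L2hgdh kept its direction and a p under 0.05, before any adjustment, in all 315 alternative values. Adjusted over all genes it changed sides in 21: it lost its call in 10 (4 in the distal convoluted tubule, 3 in principal cells and 1 each in endothelium, cluster 28 and smooth muscle) and gained it in 11 (6 in the loop of Henle, 3 in the proximal tubule and 2 in all cells). Of 615 alternative values of 31 named genes 505 kept theirs, 82 no longer passed and 28 newly passed, and of 1498 values of 100 list results 1227, 253 and 17, with 1 reversed: G2/M in endothelium passed upward without L2HGDH-OE replicate 2 (camera adjusted p = 1.11e-05, range over left-out libraries 1.11e-05 to 0.13). A minimum of 50 cells changed nothing, since no class sum held fewer. Whether depth limits the calls was not decided, since thinning lowered the count in some classes and raised it in others. In simulated data the small juxtaglomerular sums (0.135 to 0.408 M UMIs) gave back 40.3% of 2-fold changes against 23.9% in all cells. Only genes past the filter on low counts were changed there, so these shares do not speak to depth. That filter left 3143 genes in cluster 28 and 5281 in juxtaglomerular cells, against 14824 in all cells. The cause was not tested for the changes below, save that fewer libraries or genes enter some fits.

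The 0 genes in all cells became 70 with DESeq2, 1 with the same cell number of every class and 12 in the larger library set. Called lists fell to 0 in all cells and in all 14 classes with the estimated correlation, and with fry to 0 except principal cells 1, juxtaglomerular cells 2 and podocytes 1. Among libraries with Xist at 0 and with the library set as covariate B cells gave 3 lists and macrophages 5, and the mitochondrial share as covariate gave 7 in the loop of Henle.

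The 72 genes of the classes together became 911 without the filter on low counts, 673 with DESeq2, 1748 with the replicate block, 2083 with Xist as covariate, 154 over genes above 0 in every library, 1774 among libraries with Xist at 0, 221 with the library set as covariate, 209 in the larger set and 475 in the smaller. Without the filter on low counts B cells gave 121, intercalated 74, principal 2, fibroblasts 45, juxtaglomerular 226, macrophages 120, cluster 28 238, podocytes 25, smooth muscle 20 and cluster 30 36. DESeq2 gave intercalated 55, principal 33, distal convoluted tubule 21, endothelium 83, fibroblasts 29, loop of Henle 12, macrophages 7, cluster 28 77, podocytes 114, proximal tubule 27, smooth muscle 172 and cluster 30 2. The replicate block gave B cells 7, intercalated 252, principal 65, distal convoluted tubule 267, endothelium 41, fibroblasts 27, juxtaglomerular 106, macrophages 6, podocytes 592, smooth muscle 362 and cluster 30 11, though pairing by these numbers was not established. Xist as covariate gave intercalated 142, principal 16, distal convoluted tubule 1208, endothelium 8, fibroblasts 11, juxtaglomerular 177, macrophages 16, cluster 28 43, podocytes 24, proximal tubule 337, smooth muscle 43 and cluster 30 55. Libraries with Xist at 0 gave B cells 6, intercalated 195, principal 19, distal convoluted tubule 870, endothelium 19, fibroblasts 20, juxtaglomerular 156, macrophages 26, podocytes 114, proximal tubule 184, smooth muscle 99 and cluster 30 48. Genes above 0 in every library gave B cells 1, fibroblasts 7, loop of Henle 1, cluster 28 77 and smooth muscle 15, and robust dispersion fibroblasts 7 and cluster 28 34. The library set as covariate gave intercalated 57, fibroblasts 3, juxtaglomerular 44, macrophages 8, cluster 28 38, podocytes 61 and smooth muscle 1. Thinning gave loop of Henle 1, macrophages 1, cluster 28 6 and smooth muscle 14, and the stricter cell filter cluster 28 2.

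With each library left out in turn, called genes ranged over 24 (without WT replicate 2) to 799 (without L2HGDH-OE replicate 4) in the classes together. They ranged over 3 to 27 in B cells, 1 to 114 in intercalated cells, 0 to 7 in principal cells, 0 to 20 in the distal convoluted tubule, 1 to 46 in endothelium, 1 to 26 in fibroblasts, 5 to 169 in juxtaglomerular cells and 0 to 1 in the loop of Henle. The ranges were 1 to 5 in macrophages, 1 to 35 in cluster 28, 4 to 190 in podocytes, 1 to 182 in smooth muscle, 1 to 2 in cluster 30 and 0 to 6 for proximal tubule against other cells. The highest came without L2HGDH-OE replicate 4, except in B cells (WT replicate 3), cluster 28 and the last comparison (WT replicate 1). Called lists ranged over 8 to 14 in fibroblasts, 5 to 10 in macrophages, 7 to 13 in smooth muscle and 3 to 9 in cluster 30.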

Other observations

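The lists below were fixed before the data were examined and no test of an explanation is reported here. Metabolic lists beyond the respiratory chain moved in several classes of L2HGDH-OE libraries. TCA cycle genes were lower in 7 classes (adjusted p from 0.291 to 0.999 with an estimated correlation), mitochondrially encoded mRNAs in 5 (0.431 to 0.998) and glycolysis genes in 8 and higher in 1, cluster 28 (0.218 to 0.988). Cholesterol synthesis was lower in 3 of 13 classes (0.352 to 0.916), gluconeogenesis in 2 of 12 (0.379 to 0.991) and proximal tubule transporters in 4 of 10 (0.337 to 0.881), while fatty acid oxidation was higher in 2 (0.457 to 0.997). In juxtaglomerular cells 5 complex I genes, Ndufa1 (log2 −1.24) among them, and 15 genes of complexes III to V were lower adjusted over the list alone, and 0 over all genes.

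Amino acid sensing genes were higher in 8 classes (adjusted p from 0.174 to 0.997 with an estimated correlation), demethylases with TET enzymes in 8 (0.416 to 0.836), tubule injury genes in 9 (0.140 to 0.871) and nephrogenesis genes in 6 of 12 (0.248 to 0.916). Hypoxia targets were higher in 2 classes, cluster 28 among them, with Slc2a1 at 119 ± 28.3 against 47.9 ± 12.1 CPM (0.218 to 0.998), though the neutrophil gene S100a9 was there at 41980 against 8371 CPM. Interferon genes were higher in 3 of 12 (0.0847 to 0.946), MHC genes in 2 (0.352 to 0.991), NRF2 targets in 1 (0.320 to 0.986) and fibrosis genes in 2 and lower in 1, juxtaglomerular cells (0.174 to 0.976). Imprinted growth genes were higher in 1 and lower in 1 of 11 (0.291 to 0.812), the unfolded protein response was lower in 1 (0.439 to 0.971) and 2-hydroxyglutarate metabolism was called in 0 of 14 (0.662 to 0.997). S phase genes were lower in 9 of 12 (0.416 to 0.988), but without L2HGDH-OE replicate 2 the call held in 5 of these 9; without it the difference in mean log2(CPM + 1) turned from −0.40 to 0.11 in the loop of Henle and went from −0.51 to −0.05 in endothelium. The sex-linked list was called lower in 11 of 11 (0.320 to 0.540). In podocytes Cenpf (log2 −2.35), Top2a (−1.03) and Mki67 (−1.07) were lower adjusted over the list alone, and in cluster 28 Hspa1a (−1.42), Hspa1b (−1.86) and Jun (−0.89) were, with 0 of these over all genes.

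Hbb-bs, a blood haemoglobin gene, was at 19.6 and 27.8 CPM in L2HGDH-OE replicates 3 and 4, 1.06, 69.0 and 69.1 CPM in WT replicates 1 to 3, and listed at 0 in L2HGDH-OE replicates 1 and 2. Malat1, a nuclear RNA, was at 51200, 46100 and 48460 CPM in L2HGDH-OE replicates 1 and 2 and WT replicate 1, and at 26050 to 27190 CPM in the other 4 libraries. The Y gene Ddx3y was at 76.4 to 123 CPM in the 5 libraries without Xist. Clusters 20 (loop of Henle), 25 (proximal tubule) and 32 (smooth muscle) were those led by proliferation genes. Smooth muscle clusters 4 and 32 held none of the smooth muscle markers among their leading genes, cluster 4 being led by Zmat4, Sfrp2 and Itga8, while cluster 18 held 4.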
